A study of Mus musculus with 56 samples.

How the data were processed

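Spleen CD4 T cells of C57BL/6 mice were profiled as naive or mature cells without activation, or after activation with beads against CD3 and CD28. RNA was turned into 3′ end libraries with indexed poly-T primers that carry unique molecular identifiers and with linear amplification by T7 RNA polymerase, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, FastQC 0.11.7, HISAT 0.1.5, STAR 2.5.2b, HTSeq 0.9.1 and the mouse genome build mm9. Which aligner made which table, whether the molecular identifiers were collapsed, the annotation, the strand setting and any filter are not given in the sources used here. The values are deposited as raw counts per gene symbol, with 1 column per library, and the whole numbers and unequal library totals show no further scaling. If reads rather than molecules were counted, copies from amplification would add spread between replicates, which the tests estimate from the replicates either way. Library pairs of the same group differed by 1.32 to 16.5 times the variance that counting alone gives (chi-square per degree of freedom), so the counting intervals given below cover counting error only.

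Experiment 1 holds 19791 gene symbols (5620 with 0 counts in every library) in 18 libraries of 58750 to 1738555 counts. Experiment 2 holds 24421 symbols (8924 with 0 counts everywhere) in 38 libraries of 587118 to 3359875 counts. Ribosomal protein genes take 0.659 to 1.2% of the counts in experiment 1 and 24.8 to 45.1% in experiment 2, so the tables were never joined in a fit. Of 9514 symbols with over 50 counts in experiment 1, 36 have the same counts as another symbol (both names of a pair of hemoglobin genes, for example), and in experiment 2 none of 10505 do. Symbols that spreadsheet software had turned into dates were left as they stand. The reference on hand is of another build, so no genome coordinates are given.

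Groups follow the labels: cell type or sort, hours after activation and starting concentration. Titles in experiment 2 carry a second number, 1 or 2, whose meaning is not given in the sources used here. The high concentration at 72 h has number 1 alone and the low concentration number 2 alone, and at 30 h every library has number 2. At 48 h the high concentration has number 2 alone and 2 of the 3 low libraries number 1, and CD62L positive cells have number 1 alone and 2 of the 3 negative libraries number 2. Whether libraries of a group come from separate mice or cultures is also not given in the sources used here, so the p-values measure only the spread between these libraries.

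Each experiment was fitted once in edgeR 4.0.16 (R 4.3.3) with 1 coefficient per group, TMM normalisation, filterByExpr with its minimum count of 10, and the robust quasi-likelihood fit. This tested 8961 genes in experiment 1 (12 residual degrees of freedom, common dispersion 0.0147) and 9239 in experiment 2 (25 degrees of freedom, 0.0268). The 19 comparisons, their tests, the gene lists and the alternatives were chosen before the data were examined, except where a choice is said to come after. Genes passed at a Benjamini-Hochberg adjusted p of 0.05 within a comparison. SE was derived from the log2 difference and the F statistic. Against a group with 0 counts a fold is a lower bound over a floor of 3 counts over the group. With 1 to 3 counts a ratio with its exact 95% interval is given.

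Named genes follow a fixed rule. For mature against naive, 18 h against naive, 72 h against 18 h, and the means of times of the CD62L and concentration comparisons, they are the 6 largest rises and 6 largest falls among genes at or above the median expression that moved the same way at every time. To these come up to 4 members per list with the smallest adjusted p and a fixed set of T-cell genes. A comparison at 1 time adds its 3 largest rises and falls, and a test of change with time its 5 smallest adjusted p. Most genes whose call an alternative ended were left out of the text, a choice made after the data were seen. The 27 lists cover naive and central memory, effector, early activation, IL-2 and STAT5, IL-6 and STAT3, type I interferon, interferon gamma with antigen presentation, Th1, Th2, Th17, regulatory and follicular helper genes, cytokines, coinhibitory receptors, glycolysis, hypoxia, oxidative phosphorylation, replication, mitosis, ribosome biogenesis, amino acid stress, cholesterol, p53, and markers of B cells, CD8 and NK cells, myeloid cells and red cells with platelets. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A list of 20 lung-expressed genes was added after the data were seen, adjusted over its 5 comparisons. Genes called in experiment 1 were tested as lists in comparisons that share no library with the ones that gave them, adjusted over those tests; 1 gene not reported here was left out of those lists and of the correlations across genes.

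Alternatives were RLE normalisation, DESeq2 1.42.0, no low-count filter, a fit of the compared groups alone, the replicate number as a block, the second title number as a term, each library left out in turn and camera with an estimated correlation. Added after the data were seen were the level of lung transcripts as a term, the concentration comparison without 72 h, and the 48 h comparison with each low library alone. Group labels were also exchanged among the libraries compared, in every way where there are few and in 40 ways otherwise. On simulated counts with the same depths and spread, edgeR recovered 40.3, 82.1 and 97% of genes changed 1.5-, 2- and 4-fold in the mean CD62L comparison of experiment 1. For the mean concentration comparison these were 55.2, 79.1 and 98.5%, and for 18 h alone 8.96, 41.8 and 81.8%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.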

Results

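Gene expression was measured in mouse CD4 T cells by RNA sequencing of 3′ transcript ends with molecular identifiers, per the labels' protocols. There are 56 libraries in 19 groups, deposited as 2 count tables, here called experiment 1 and experiment 2. Spleen CD4 T cells of C57BL/6 mice were activated with beads that carry antibodies to CD3 and CD28, without added cytokines. The submitters ask how the concentration of the cells in culture relates to their early memory differentiation. Experiment 1 has 18 libraries in 6 groups of 3: unactivated naive cells (CD44 negative, CD62L positive), unactivated mature cells (CD44 positive, CD62L negative), and activated cells sorted as CD62L positive or negative at 48 and 72 h. Experiment 2 has 38 libraries in 13 groups: naive cells, cells started at a high (1000000 per ml) or low (62500 per ml) concentration and taken at 18, 30, 48 and 72 h, and cells sorted by CD62L at 48 and 72 h. The sorted cells of both experiments came from cultures started at 250000 cells per ml. Each group has 3 libraries except the low concentration at 72 h, which has 2.

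Values are log2 differences ± SE. The SE is the size of the difference over the square root of the F statistic, so it restates the test. Where 1 side has few counts it can be smaller than counting error alone. Examples are Il2 in naive cells of experiment 2 (0 to 1.244 CPM) and Ctsw at the high concentration at 18 h (0.746 to 2.795 CPM). A gene is called higher or lower, or said to rise or fall, where edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. List members not counted as higher or lower did not pass that test. Library totals run from 58750 to 1738555 counts in experiment 1 and from 587118 to 3359875 in experiment 2.

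**Figure D1:**
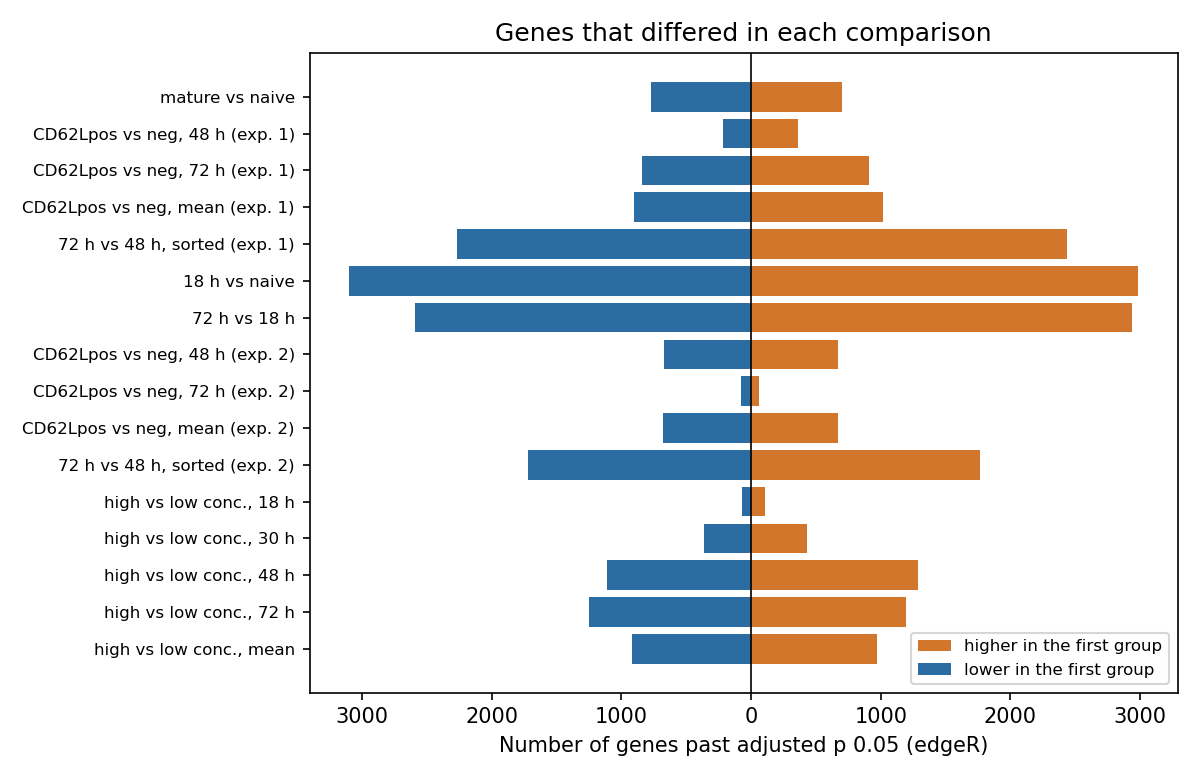
Number of genes higher (right) or lower (left) past edgeR's adjusted p of 0.05 in each comparison of groups, with 1 pair of bars per comparison and the tests of change with time not drawn. The drawn counts run from 141 genes for CD62L positive against negative cells at 72 h in experiment 2 to 6087 genes for 18 h against naive cells.

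The first 18 h of activation were compared with naive cells in experiment 2, over both concentrations. Il2, the T-cell growth factor gene, rose by 8.71 ± 0.41 and Irf4, a transcription factor induced through the antigen receptor, by 7.64 ± 0.21 (n = 6 activated and 3 naive libraries). The costimulatory receptor gene Tnfrsf4 rose by 5.24 ± 0.20 and the growth regulator Myc by 2.32 ± 0.21. Some induced genes had 0 counts in every naive library, so only a lower bound stands, against a floor of 3 counts over the group. Lad1 was at least 979-fold higher, the chemokine gene Ccl4 at least 317-fold and the growth factor gene Pdgfb at least 118-fold. The cytokine gene Tnfsf11 was at least 107-fold higher and the transcription factor gene Bhlhe40 at least 100-fold. Klf2, a transcription factor of quiescent and recirculating T cells, changed by -4.76 ± 0.18, and the egress receptor gene S1pr1 by -5.38 ± 0.22. The interferon-induced genes Irf7 and Zbp1 changed by -6.69 ± 0.27 and -5.30 ± 0.21. In all, 6087 of 9239 genes tested passed, 2985 higher and 3102 lower at 18 h.

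Growth and cell-cycle genes rose over those 18 h. Srm, spermidine synthase, rose by 3.25 ± 0.15 and Gnl3, a nucleolar protein gene, by 3.06 ± 0.17. The ribosome biogenesis list had 24 of 24 members higher (24 adjusted over the list alone, camera adjusted p = 3.26e-13). Gins2 and Mcm3, of the replicative helicase, rose by 4.83 ± 0.21 and 3.72 ± 0.18. DNA replication had 22 of 25 members higher (23 adjusted over the list alone, camera adjusted p = 7.7e-13), and mitosis 21 of 23 members higher and 1 lower (21 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.32e-06). Early activation had 21 of 27 members higher and 3 lower (21 higher and 3 lower adjusted over the list alone, camera adjusted p = 5.38e-07). Among cytokine genes, 14 of 17 members were higher and 2 lower (14 higher and 2 lower adjusted over the list alone, camera adjusted p = 6e-05). Oxidative phosphorylation had 21 of 25 members higher and 1 lower (21 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.31e-05). Glycolysis had 14 of 17 members higher and 1 lower (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00113). Cholesterol synthesis had 11 of 18 members higher and 1 lower (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00144), and its member Sqle rose by 3.79 ± 0.30. Genes of resting cells and of the interferon response fell. Il7r, the IL-7 receptor gene, changed by -7.26 ± 0.41, and the transcription factor genes Lef1 and Tcf7 by -2.34 ± 0.18 and -1.92 ± 0.16. In the naive and central memory list, 2 of 24 members were higher and 20 lower (2 higher and 20 lower adjusted over the list alone, camera adjusted p = 2.44e-08). Type I interferon response had 23 of 24 members lower (23 adjusted over the list alone, camera adjusted p = 2.94e-11). Of the interferon gamma and antigen presentation list, 3 of 25 members were higher and 20 lower (3 higher and 20 lower adjusted over the list alone, camera adjusted p = 6.47e-07).

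Between 18 and 72 h, over both concentrations, mitotic genes rose and receptor-induced genes fell. Ube2c, an enzyme of mitotic exit, rose by 5.69 ± 0.19 and Birc5, survivin, by 4.08 ± 0.13 (n = 6 libraries at 18 h and 5 at 72 h). Lgals1 (galectin-1) rose by 5.00 ± 0.16 and Anxa2, annexin A2, by 4.16 ± 0.16. Drc1, of a ciliary dynein complex, rose by 5.67 ± 0.19, and Mxd3, a partner of Max, by 5.59 ± 0.24. Socs2, induced downstream of STAT5, rose by 5.08 ± 0.15. Ccl4 and Il2 changed by -5.21 ± 0.22 and -4.99 ± 0.23. Irf4 and the activation marker Cd69 changed by -4.19 ± 0.13 and -3.28 ± 0.17. Klf2 rose again, by 2.82 ± 0.17. The mitosis list had 22 of 23 members higher (22 adjusted over the list alone, camera adjusted p = 3.27e-14). Ribosome biogenesis had 24 of 24 members lower (24 adjusted over the list alone, camera adjusted p = 1.63e-16). Type I interferon response had 17 of 24 members higher and 2 lower (18 higher and 2 lower adjusted over the list alone, camera adjusted p = 9.43e-06). Hypoxia had 13 of 18 members higher and 2 lower (13 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00141). The interferon and hypoxia rises were larger at the high concentration. The median difference of high minus low went from 0.231 at 18 h to 2.05 at 72 h for type I interferon. For hypoxia it went from -0.081 to 2.75. The rise at the low concentration alone was not tested. Early activation had 6 of 27 members higher and 19 lower (6 higher and 19 lower adjusted over the list alone, camera adjusted p = 9.43e-06). The regulatory T-cell list had 10 of 14 members higher and 2 lower (10 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00147). Its members include Capg, an actin-capping protein gene, which rose by 2.37 ± 0.11. In all, 5532 genes passed, 2942 higher and 2590 lower at 72 h.

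The concentration comparison sets cultures started at 1000000 cells per ml against cultures started at 62500 cells per ml, a 16-fold difference. Averaged over the 4 times, Ndrg1, a gene induced at low oxygen, was higher at the high concentration by 2.29 ± 0.12 (n = 12 high and 11 low libraries). The lactate exporter gene Slc16a3 was higher by 2.28 ± 0.16 and the glucose transporter gene Slc2a3 by 2.16 ± 0.11. Mgarp, a mitochondrial protein gene, differed by 3.36 ± 0.27 and the metallothionein gene Mt1 by 2.74 ± 0.23. The fatty-acid desaturase gene Scd2 differed by 2.03 ± 0.10 and Gimap7, a lymphocyte GTPase gene, by 1.87 ± 0.12. Ctsw, cathepsin W, was lower at the high concentration (-3.70 ± 0.21), as was Pdgfb (-1.91 ± 0.18). The transcription factor genes Irf8 and Zbtb32 stood at -1.81 ± 0.12 and -1.72 ± 0.16, and the cell-cycle inhibitor gene Cdkn1a at -1.17 ± 0.11. Il2, Il6ra and Tcf7 were not past the test, at -0.25 ± 0.16, 0.11 ± 0.12 and -0.056 ± 0.11. By time Il2 was lower at 48 h, at -2.54 ± 0.28, and not past the test at 18, 30 or 72 h, at 0.74 ± 0.22, -0.28 ± 0.22 and 1.07 ± 0.44, though at 18 and 72 h it passed as higher by DESeq2, without the low-count filter and in the compared groups alone. Over 18, 30 and 48 h alone, a choice made after seeing the data, it passed at -0.69, which rests on 48 h. Over the 4 times 1895 genes passed, 974 higher and 921 lower.

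The glycolysis, hypoxia and cholesterol lists had most members higher in that mean. Aldoa, a glycolytic enzyme gene, was higher by 0.96 ± 0.072 and Slc2a1, a glucose transporter gene, by 1.38 ± 0.098. The glycolysis list had 16 of 17 members higher (17 adjusted over the list alone, camera adjusted p = 4.13e-21). Its member Gapdh, which has many pseudogenes, differed 47.7- to 120-fold in CPM between libraries of the same group in 6 groups, and its counts are uncertain. Egln3, an oxygen-sensing prolyl hydroxylase gene, was higher by 2.28 ± 0.18. Hypoxia had 16 of 18 members higher and 1 lower (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.2e-18). Fdps and Hmgcs1 of the mevalonate pathway were higher by 1.21 ± 0.077 and 1.02 ± 0.075. Cholesterol synthesis had 17 of 18 members higher (18 adjusted over the list alone, camera adjusted p = 1.37e-17). The immunoproteasome subunit gene Psmb9 was higher by 0.82 ± 0.089 and the interferon-induced genes Isg15 and Isg20 by 2.00 ± 0.23 and 1.61 ± 0.14. Of the interferon gamma and antigen presentation list, 18 of 25 members were higher (20 adjusted over the list alone, camera adjusted p = 4.15e-13). Type I interferon response had 13 of 24 members higher (14 adjusted over the list alone, camera adjusted p = 3.15e-12). In the naive and central memory list, 10 of 24 members were higher and 3 lower (12 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00232). The amino acid stress list had 9 of 22 members higher and 1 lower (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000398). The median of that list was 0.06 at 18 h and 0.229 at 72 h. Oxidative phosphorylation had 8 of 25 members lower (11 adjusted over the list alone, camera adjusted p = 0.00153). Srm and Bop1, of ribosome production, were lower, at -0.79 ± 0.076 and -0.65 ± 0.08. The ribosome biogenesis list had 19 of 24 members lower (21 adjusted over the list alone, camera adjusted p = 4.26e-14). The IL-6 and STAT3 list had 5 of 17 members higher and 1 lower (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.142). Its median went from -0.281 at 18 h to 0.432 at 72 h (camera adjusted p = 0.0138 for the change, a contrast chosen after seeing the data).

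**Figure D2:**
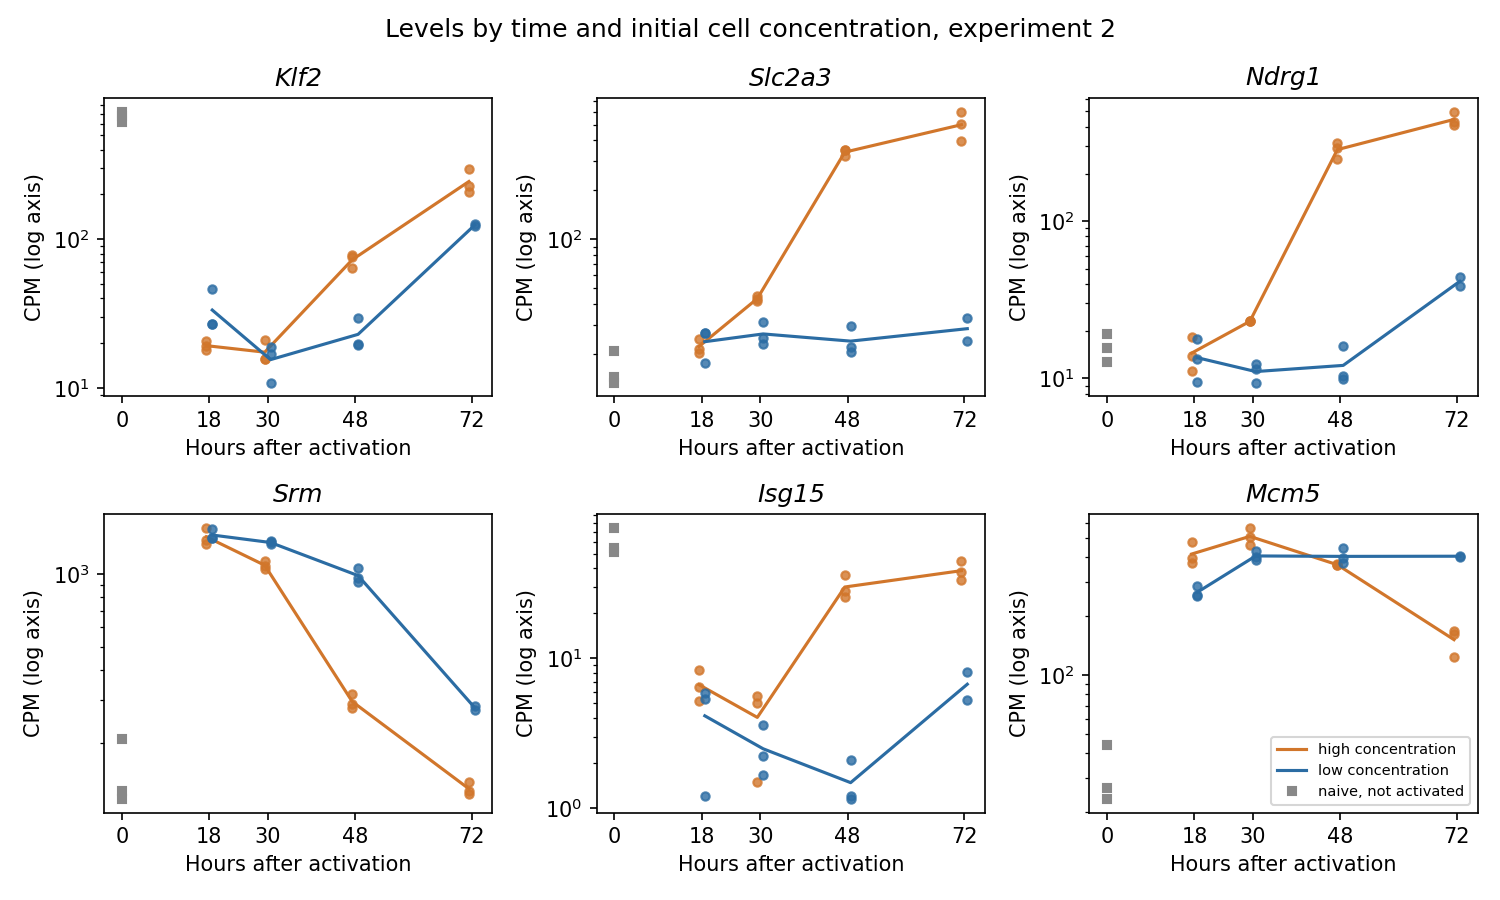
CPM (log axis) against hours after activation for 6 genes, with 1 dot per library of the high or low concentration, lines through the group means and squares for naive cells at 0 h. Slc2a3 and Ndrg1 part most between the concentrations at 48 and 72 h, by 3.81 and 4.52 log2 units at 48 h.

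At 18 h replication and mitosis genes were higher at the high concentration. Ctsw, Cd72, a lectin-type receptor gene, and Irf8 were lower at the high concentration, at -4.97 ± 0.43, -3.54 ± 0.31 and -2.18 ± 0.23 (n = 3). The ribonucleotide reductase gene Rrm2 was higher by 1.55 ± 0.28, Gins2 by 0.97 ± 0.15, Mcm3 by 0.74 ± 0.16 and Lrr1 by 2.79 ± 0.56. The replication list had 14 of 25 members higher (22 adjusted over the list alone, camera adjusted p = 5.03e-20), and mitosis 6 of 23 members higher (9 adjusted over the list alone, camera adjusted p = 4.41e-14). Cholesterol synthesis, with a median of 0.37, was higher as a list and had 0 of 18 members past the test (0 adjusted over the list alone, camera adjusted p = 0.0272). Of the interferon gamma and antigen presentation list, 1 of 25 members were higher (1 adjusted over the list alone, camera adjusted p = 0.0374). Hypoxia had 1 of 18 members lower (1 adjusted over the list alone, camera adjusted p = 0.529). In all 173 genes passed, 106 higher and 67 lower. Fitting the compared groups alone gave 455 genes. Leaving out a library gave 104 (high concentration, replicate 3), 94 (low, replicate 1) or 115 (low, replicate 2).

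At 30 h glycolysis and hypoxia genes were higher at the high concentration. The lactate exporter gene Slc16a3 was higher by 2.94 ± 0.25, the desaturase gene Scd2 by 2.34 ± 0.18, Mt1 by 2.02 ± 0.27 and Ndrg1 by 1.05 ± 0.23 (n = 3). Gimap7 was higher by 2.50 ± 0.23. Ctsw, Cd72 and Irf8 stood at -4.73 ± 0.39, -3.93 ± 0.33 and -2.61 ± 0.21. The chemokine receptor gene Ccr7 was lower, at -0.66 ± 0.12. Cholesterol synthesis had 11 of 18 members higher (15 adjusted over the list alone, camera adjusted p = 1.36e-11). Glycolysis had 9 of 17 members higher (11 adjusted over the list alone, camera adjusted p = 7.67e-11). Hypoxia had 6 of 18 members higher (7 adjusted over the list alone, camera adjusted p = 9.01e-05). Of the interferon gamma and antigen presentation list, 11 of 25 members were higher (13 adjusted over the list alone, camera adjusted p = 1.62e-10). In all 791 genes passed, 428 higher and 363 lower. Without replicate 3 of the high concentration 470 genes passed, and without replicate 2 of the low concentration 522.

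By 48 h Egln3 and Ndrg1, both induced at low oxygen, were higher at the high concentration by 4.58 ± 0.22 and 4.52 ± 0.20 (n = 3). The glucose transporter gene Slc2a3 was higher by 3.81 ± 0.19, Anxa2 by 3.70 ± 0.19 and Mt1 by 5.10 ± 0.26. Klf2 was higher by 1.65 ± 0.22 and Isg15 by 4.27 ± 0.41. The integrin gene Itga7 had 268 counts in the high libraries and 3 in the low ones, a ratio of 109 with a 95% counting interval of 36.9 to 532. Il2 and Ccl4 were lower, at -2.54 ± 0.28 and -3.71 ± 0.26. So were Srm, at -1.73 ± 0.15, and Rpph1, the RNA of ribonuclease P, at -4.73 ± 0.23. How well poly-T priming captures Rpph1 was not tested, so its counts are uncertain as a measure of its level here and below. Hypoxia had 15 of 18 members higher (15 adjusted over the list alone, camera adjusted p = 2e-14). Glycolysis had 17 of 17 members higher (17 adjusted over the list alone, camera adjusted p = 2.72e-14). The IL-2 and STAT5 list had 17 of 22 members higher and 4 lower (17 higher and 5 lower adjusted over the list alone, camera adjusted p = 5.02e-06). Its median lay on the other side at 18 h (-0.168) and 72 h (-0.273). In the naive and central memory list, 12 of 24 members were higher and 3 lower (13 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.00104). The amino acid stress list had 12 of 22 members higher (13 adjusted over the list alone, camera adjusted p = 8.42e-08). Ribosome biogenesis had 21 of 24 members lower (22 adjusted over the list alone, camera adjusted p = 2.72e-14). In all 2397 genes passed, 1286 higher and 1111 lower. Fitting the compared groups alone gave 1488 genes. Keeping 1 low library at a time gave 917 (replicate 1, whose title carries the second number of the high libraries) and 1340 and 1452 (replicates 2 and 3, which carry the other number). That choice was made after seeing the data, and the lone library is assumed to vary like the other groups.

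At 72 h the metabolic differences stood beside a reversal in the replication genes. Mgarp was higher at the high concentration by 5.94 ± 0.43, Itga7 by 7.24 ± 0.53, Egln3 by 4.84 ± 0.30 and Slc2a3 by 4.13 ± 0.23 (n = 3 high and 2 low libraries). The receptor-induced genes Cd69, Nr4a1 and Irf4 were higher by 1.40 ± 0.28, 1.55 ± 0.25 and 0.89 ± 0.19. Mcm5, Fen1, Gins2 and Rrm2, of DNA replication, were lower, at -1.42 ± 0.17, -1.28 ± 0.16, -1.14 ± 0.15 and -1.59 ± 0.22. The cytokine gene Lta was lower too, at -2.10 ± 0.15, and Nup93, a nuclear pore protein gene, at -2.32 ± 0.28. Hmgn2 stood at -3.63 ± 0.30, but it has many near-identical pseudogene copies and its counts are uncertain. Replication had 19 of 25 members lower (20 adjusted over the list alone, camera adjusted p = 1.15e-12), and mitosis 9 of 23 members lower (10 adjusted over the list alone, camera adjusted p = 0.000471). Hypoxia had 15 of 18 members higher (15 adjusted over the list alone, camera adjusted p = 2.13e-16). Glycolysis had 15 of 17 members higher (15 adjusted over the list alone, camera adjusted p = 2.52e-16). Type I interferon response had 18 of 24 members higher (19 adjusted over the list alone, camera adjusted p = 1.09e-10). Early activation had 13 of 27 members higher and 2 lower (14 higher and 2 lower adjusted over the list alone, camera adjusted p = 7.79e-06). In all 2447 genes passed, 1197 higher and 1250 lower. With the second title number as a term 1531 passed. Without replicate 1 or 2 of the low concentration 1421 and 1442 passed, but a lone library is then assumed to vary like the other groups.

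**Figure D3:**
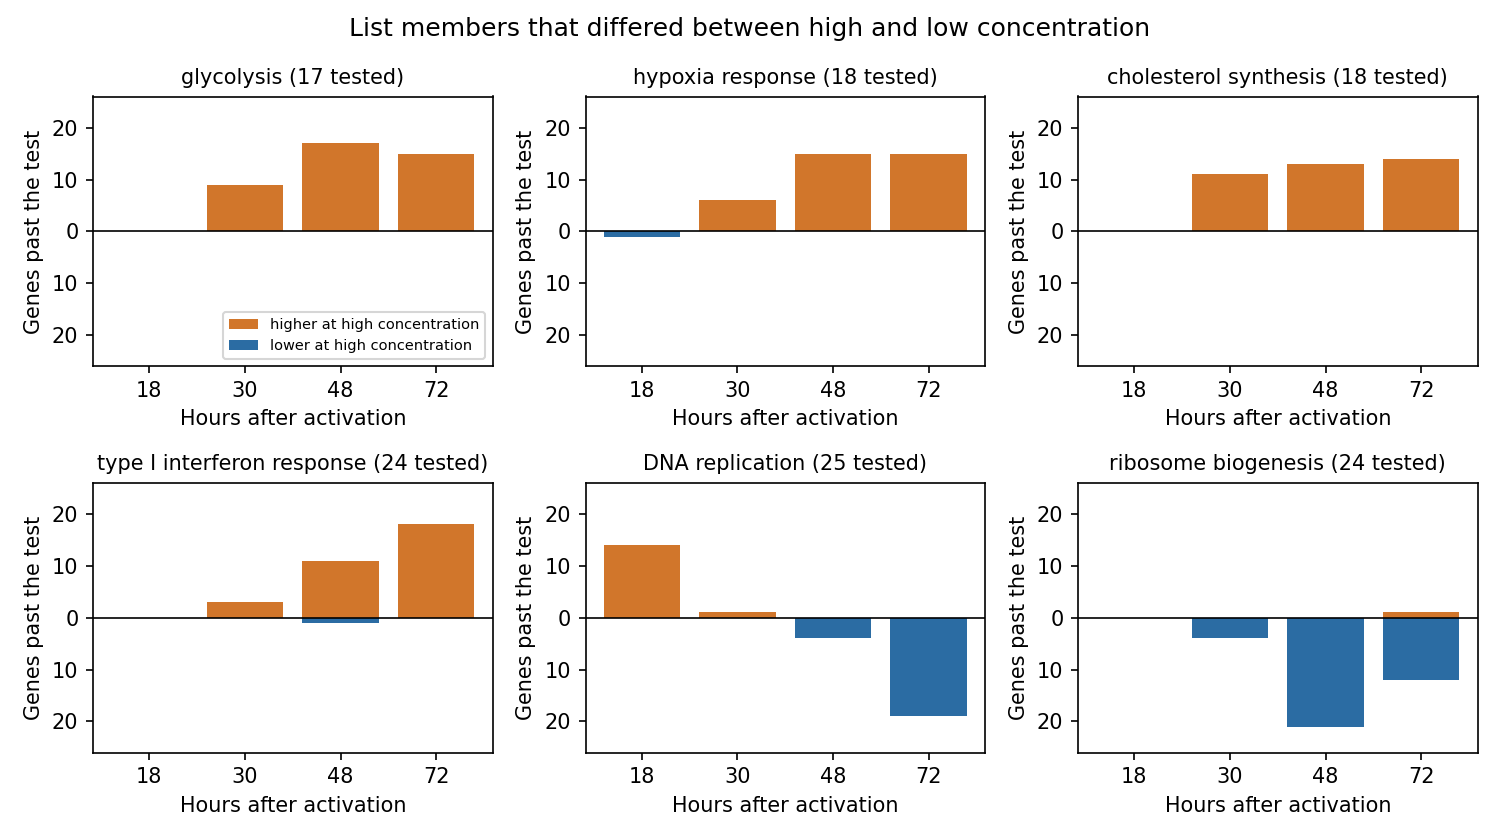
Number of list members past edgeR's adjusted p of 0.05 that were higher (up) or lower (down) at the high concentration, at 18, 30, 48 and 72 h, for 6 lists. Replication has 14 of 25 members higher at 18 h and 19 of 25 lower at 72 h.

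The concentration difference itself changed between 18, 30, 48 and 72 h for 2821 genes (edgeR F test on the time-by-concentration terms). At 18 h Slc2a3 had 20.14 to 24.73 CPM in the high libraries and 17.53 to 26.75 in the low ones. At 30 h it had 41.85 to 44.95 and 23.04 to 31.23 CPM. Its difference stood at 3.81 ± 0.19 at 48 h and 4.13 ± 0.23 at 72 h (adjusted p = 1.92e-16 over the 4 times). Anxa2 went from -0.75 ± 0.31 at 18 h through 3.70 ± 0.19 at 48 h to 1.89 ± 0.19 at 72 h (adjusted p = 6.46e-14). Egln3 had an adjusted p = 3.19e-15, the ribonuclease P gene Rpph1 an adjusted p = 9.79e-18 and 2410006H16Rik an adjusted p = 7.12e-15. Ccl4 stood at -3.71 ± 0.26 at 48 h and 0.55 ± 0.49 at 72 h. Without the 72 h libraries, a choice made after seeing the data, 1562 genes changed over the other times.

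Sorted cells were compared to ask how activated cells that carry CD62L differ from those that do not. In experiment 1, averaged over 48 and 72 h, Klf2 and its target gene S1pr1 were higher in CD62L positive cells by 1.41 ± 0.11 and 1.71 ± 0.13 (n = 6 libraries per side), and the transcription factor gene Tcf7 by 0.93 ± 0.15. Cd27, a costimulatory receptor gene, was higher by 1.24 ± 0.093 and Rasa3, which switches off Ras and Rap, by 1.93 ± 0.14. Arl5c was higher by 2.10 ± 0.14 and Pde2a, a phosphodiesterase gene, by 2.05 ± 0.37. Il2 was lower (-3.46 ± 0.21), as were Penk, the enkephalin precursor gene (-3.15 ± 0.19), and Lad1 (-2.23 ± 0.12). Asb2, a ubiquitin ligase subunit gene, stood at -2.06 ± 0.27, the granule protein gene Nkg7 at -1.67 ± 0.27 and Serpine2 at -1.80 ± 0.15. Irf4 and Cdkn1a stood at -1.09 ± 0.095 and -1.82 ± 0.11. Tbx21, the Th1 regulator gene, was not past the test, at -0.14 ± 0.12. In all 1921 of 8961 genes tested passed, 1016 higher and 905 lower. Which direction has more genes depends on the scaling (52.9% higher, but 48.7% with RLE normalisation and 49.3% by DESeq2).

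Lists of resting-cell and interferon genes were higher in those CD62L positive cells, and growth lists lower. Of the naive and central memory list, 23 of 25 members were higher (23 adjusted over the list alone, camera adjusted p = 1.52e-19, adjusted p = 0.00117 with an estimated correlation). Zbp1 and the GTPase gene Gbp7, both induced by interferons, were higher by 1.68 ± 0.15 and 1.20 ± 0.097. Of interferon gamma response with antigen presentation, 20 of 26 members were higher (21 adjusted over the list alone, camera adjusted p = 1.35e-12). Type I interferon response had 15 of 26 members higher (16 adjusted over the list alone, camera adjusted p = 5.79e-11). The cytokine list had 1 of 21 members higher and 10 lower (1 higher and 10 lower adjusted over the list alone, camera adjusted p = 1.12e-06). Early activation had 1 of 25 members higher and 11 lower (1 higher and 12 lower adjusted over the list alone, camera adjusted p = 4.86e-06, adjusted p = 0.0445 with an estimated correlation). The effector list had 2 of 24 members higher and 9 lower (2 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.000955, adjusted p = 0.0559 with an estimated correlation). Srm and the asparagine synthetase gene Asns were lower, at -1.06 ± 0.11 and -1.49 ± 0.17. Ribosome biogenesis had 15 of 23 members lower (19 adjusted over the list alone, camera adjusted p = 4.21e-10). The amino acid stress list had 1 of 23 members higher and 15 lower (1 higher and 17 lower adjusted over the list alone, camera adjusted p = 1.12e-06). The p53 target gene Phlda3 stood at -1.24 ± 0.12, and the p53 list had 2 of 17 members higher and 8 lower (3 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.004). Socs3, which limits STAT3 signals, and the receptor gene Il6st were higher by 1.41 ± 0.15 and 0.81 ± 0.15. The IL-6 and STAT3 list had 8 of 17 members higher and 1 lower (9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0238), a call that the fit without the low-count filter did not make (adjusted p = 0.0663). B-cell markers had 4 of 11 members higher (4 adjusted over the list alone, camera adjusted p = 0.000146, adjusted p = 0.123 with an estimated correlation), and the class II gene H2-Ab1, whose family shares sequence, stood at 1.06 ± 0.20. Of 18 lung-expressed genes tested 2 were higher (camera adjusted p = 0.00032, adjusted p = 0.332 with an estimated correlation).

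At 48 h in experiment 1, Rasa3 and Klf2 were higher in CD62L positive cells, at 2.62 ± 0.25 and 1.79 ± 0.17 (n = 3). The cytokine gene Il2, the chemokine gene Ccl4 and Penk were lower, at -4.13 ± 0.28, -4.18 ± 0.35 and -2.26 ± 0.27. Nkg7 and Lad1 were lower at -1.92 ± 0.41 and -1.84 ± 0.14. The p53 list had 7 of 17 members lower (11 adjusted over the list alone, camera adjusted p = 1.24e-07). Of the naive and central memory list, 9 of 25 members were higher (10 adjusted over the list alone, camera adjusted p = 1.45e-11). In all 583 genes passed, 363 higher and 220 lower, and 385 passed without replicate 1 of the CD62L negative cells.

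At 72 h in experiment 1 the lymphocyte surface gene Cd7 stood at 2.37 ± 0.20 in CD62L positive against negative cells, S1pr1 at 1.82 ± 0.14 and Tcf7 at 1.54 ± 0.20 (n = 3). Penk and Asb2 stood at -4.04 ± 0.28 and -2.81 ± 0.41, and Asns and Il2 at -2.71 ± 0.28 and -2.79 ± 0.32. Replication had 13 of 25 members lower (21 adjusted over the list alone, camera adjusted p = 8.32e-08). Of the naive and central memory list, 21 of 25 members were higher (22 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.52e-19). The amino acid stress list had 1 of 23 members higher and 13 lower (1 higher and 16 lower adjusted over the list alone, camera adjusted p = 7.05e-08). Markers of other cells were higher on the CD62L positive side, B-cell markers with 4 of 11 members higher (4 adjusted over the list alone, camera adjusted p = 0.000256, adjusted p = 0.123 with an estimated correlation). Myeloid markers had 2 of 16 members higher (2 adjusted over the list alone, camera adjusted p = 0.015, adjusted p = 0.287 with an estimated correlation). Of 18 lung-expressed genes tested 9 were higher (camera adjusted p = 1.08e-09, adjusted p = 0.105 with an estimated correlation). In all 1747 genes passed at 72 h, 909 higher and 838 lower, a balance that turns with the scaling (52% higher, 47.4% with RLE normalisation, 48% by DESeq2). With the level of lung transcripts as a term, a choice made after seeing the data, 834 passed. That level also parts the positive from the negative libraries, so the drop does not show how many calls lung RNA made.

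For 169 genes of experiment 1 the CD62L difference changed from 48 to 72 h, 53 upward and 116 downward. Tgm2, a transglutaminase gene, went from 1.86 ± 0.16 to -0.55 ± 0.22 (n = 3 per group). Xbp1, a transcription factor gene of the secretory pathway, went from 1.05 ± 0.18 to -1.09 ± 0.20. Cish, a feedback inhibitor of IL-2 signalling, went from 0.15 ± 0.12 to -1.24 ± 0.13. Asns went from -0.28 ± 0.19 to -2.71 ± 0.28 and the actin-binding protein gene Actn1 from 0.31 ± 0.15 to 1.94 ± 0.15. In the IL-2 and STAT5 list 9 of 24 members were lower (11 adjusted over the list alone, camera adjusted p = 4.12e-08). In replication 6 of 25 members were lower (19 adjusted over the list alone, camera adjusted p = 5.53e-11). The count is 279 without the low-count filter, 255 by DESeq2 and 35 with the level of lung transcripts as a term. That level also parts the CD62L positive from the negative libraries at 72 h. Leaving out a library gives 95 or 103 (48 h negative, replicate 1 or 2), 102 (72 h negative, replicate 2), and 79 or 256 (72 h positive, replicate 1 or 3).

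From 48 to 72 h the sorted cells of experiment 1, averaged over both sorts, raised the phosphodiesterase gene Pde2a by 3.88 ± 0.29 (n = 6 per time). Irf8 changed by -2.58 ± 0.10, the chaperone gene Hsp90aa1 by -2.49 ± 0.59 and Bcat1, which transaminates branched-chain amino acids, by -2.35 ± 0.15. Ribosome biogenesis had 21 of 23 members lower (23 adjusted over the list alone, camera adjusted p = 2.23e-14). Replication had 21 of 25 members lower (22 adjusted over the list alone, camera adjusted p = 5.3e-05). Naive and central memory genes had 21 of 25 members higher (22 adjusted over the list alone, camera adjusted p = 2.03e-10). Type I interferon response had 17 of 26 members higher and 1 lower (17 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000192). In all 4703 genes passed, 2436 higher and 2267 lower at 72 h, and which direction has more genes depends on the scaling (51.8% higher, but 45.4% with RLE normalisation and 45.6% by DESeq2).

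In experiment 2, averaged over 48 and 72 h, S1pr1 was higher in CD62L positive cells by 1.28 ± 0.17 (n = 6 per side). The cytoskeletal gene Pdlim4 was higher by 2.19 ± 0.14, the matrix protein gene Ecm1 by 1.53 ± 0.16 and the semaphorin gene Sema4a by 1.68 ± 0.17. The IL-6 receptor gene Il6ra was higher by 0.76 ± 0.16. Ccl4 and Il2 were lower, at -3.42 ± 0.35 and -3.13 ± 0.30. So were Nr4a3, an orphan receptor gene induced through the antigen receptor, at -1.97 ± 0.31, and Nrgn, a calmodulin-binding protein gene, at -2.03 ± 0.18. The mean for Il2 rests on 48 h. At 72 h Il2 had 11.52 to 20.67 CPM in the positive and 13.79 to 29.12 CPM in the negative libraries, ranges that overlap. Irf4, the inhibitory receptor gene Pdcd1 and Cdkn1a stood at -1.34 ± 0.12, -1.78 ± 0.22 and -1.77 ± 0.15. Tcf7 and Lef1 were not past the test, at 0.14 ± 0.14 and 0.25 ± 0.15. Ribosome biogenesis had 20 of 24 members lower (21 adjusted over the list alone, camera adjusted p = 4.77e-16). Early activation had 2 of 27 members higher and 16 lower (3 higher and 16 lower adjusted over the list alone, camera adjusted p = 2.28e-11). Naive and central memory genes had 13 of 24 members higher (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 7.05e-13). Mitosis had 17 of 23 members higher (19 adjusted over the list alone, camera adjusted p = 3.94e-08), and its member Top2a was higher by 0.87 ± 0.11. The amino acid stress list had 10 of 22 members lower (10 adjusted over the list alone, camera adjusted p = 4.73e-07). The p53 list had 8 of 15 members lower (1 higher and 9 lower adjusted over the list alone, camera adjusted p = 6.43e-06). The coinhibitory receptor list had 3 of 9 members lower (3 adjusted over the list alone, camera adjusted p = 0.00247). Of interferon gamma response with antigen presentation, 8 of 25 members were higher (13 adjusted over the list alone, camera adjusted p = 4.6e-05). In all 1345 genes passed, 668 higher and 677 lower.

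At 48 h in experiment 2 Il2, Ccl4 and Nr4a3 were lower in CD62L positive cells by far, at -5.98 ± 0.41, -5.61 ± 0.34 and -3.15 ± 0.34 (n = 3). Pdlim4 and Lrrc32, a carrier of latent TGF-beta, were higher, at 2.55 ± 0.22 and 2.32 ± 0.29. Early activation had 1 of 27 members higher and 17 lower (3 higher and 17 lower adjusted over the list alone, camera adjusted p = 1.34e-16). The effector list had 1 of 16 members higher and 10 lower (2 higher and 10 lower adjusted over the list alone, camera adjusted p = 6.32e-07). There were 1341 genes past the test, 668 higher and 673 lower. The count was 818 without replicate 2 of the negative cells, 847 without replicate 3 of the positive cells and 844 with the second title number as a term, which is 1 in every positive library and 2 in 2 of the 3 negative ones.

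At 72 h in experiment 2 Pdlim4 stood at 1.83 ± 0.18 in CD62L positive against negative cells and Ndrg1 at 0.98 ± 0.17 (n = 3). Nrgn stood at -1.92 ± 0.27, Asns at -2.12 ± 0.42 and Cdkn1a at -1.23 ± 0.23. Ribosome biogenesis had 6 of 24 members lower (16 adjusted over the list alone, camera adjusted p = 1.31e-15). Replication had 4 of 25 members lower (12 adjusted over the list alone, camera adjusted p = 1.91e-08). Mitosis had 4 of 23 members higher (16 adjusted over the list alone, camera adjusted p = 2.54e-08). At 72 h 141 genes passed, 63 higher and 78 lower. DESeq2 gave 229 and the compared groups alone 231. Leaving out a library gave 70 or 88 (negative cells, replicate 1 or 2) and 91, 64 or 50 (positive cells, replicate 1, 2 or 3).

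The CD62L difference of experiment 2 changed from 48 to 72 h for 120 genes, 55 upward and 65 downward. Il2, at -5.98 ± 0.41 at 48 h, changed by 5.70 ± 0.60 (n = 3 per group). Nr4a1, an early receptor-induced gene, changed by 2.80 ± 0.36. Bhlhe40 went from -2.18 ± 0.23 to 0.21 ± 0.23. The cytokine gene Lta moved the other way, by -1.64 ± 0.20, and Drc1 by -1.68 ± 0.23. In early activation 11 of 27 members were higher (15 higher and 2 lower adjusted over the list alone, camera adjusted p = 2.84e-18). In the IL-2 and STAT5 list 7 of 22 members were lower (1 higher and 11 lower adjusted over the list alone, camera adjusted p = 6.56e-07).

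Sorted cells of experiment 2 raised the integrin gene Itga7 from 48 to 72 h by 4.14 ± 0.29, Anxa2 by 3.19 ± 0.13 and S1pr1 by 2.96 ± 0.17 (n = 6 per time). Lta, Rpph1 and the receptor gene Gpr83 changed by -3.29 ± 0.11, -3.08 ± 0.16 and -2.58 ± 0.17. Ribosome biogenesis had 22 of 24 members lower (23 adjusted over the list alone, camera adjusted p = 3.52e-17). Naive and central memory genes had 19 of 24 members higher (19 adjusted over the list alone, camera adjusted p = 5.2e-13). Hypoxia had 12 of 18 members higher and 2 lower (12 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.00289). Oxidative phosphorylation had 1 of 25 members higher and 12 lower (1 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.00289). In all 3488 genes passed, 1767 higher and 1721 lower at 72 h.

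Unactivated mature cells were compared with naive cells in experiment 1. Id2, a regulator of effector cells, was higher in mature cells by 1.69 ± 0.16, the chemokine receptor gene Cxcr3 by 1.63 ± 0.20, the nuclear receptor gene Rora by 2.10 ± 0.30 and the regulatory T-cell gene Ikzf2 by 2.02 ± 0.28 (n = 3). Cd44 was higher by 1.42 ± 0.26, which matches the sort. Igfbp4, Ccr7 and Lef1, of naive cells, stood at -4.12 ± 0.23, -1.98 ± 0.15 and -1.34 ± 0.16. The largest fitted rises were of genes with few counts in the naive libraries. Bcat1 and Kif20a had 0 there and were at least 1.82-fold and 1.66-fold higher.

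The mature cells carried more of the follicular helper and effector genes. Follicular helper genes had 9 of 12 members higher (10 adjusted over the list alone, camera adjusted p = 6.3e-05). The effector list had 10 of 24 members higher (15 adjusted over the list alone, camera adjusted p = 0.00021, adjusted p = 0.0453 with an estimated correlation). The Th1 list had 7 of 10 members higher (8 adjusted over the list alone, camera adjusted p = 0.000939). Coinhibitory receptors had 6 of 12 members higher (8 adjusted over the list alone, camera adjusted p = 0.00119). Regulatory T-cell genes had 5 of 14 members higher (6 adjusted over the list alone, camera adjusted p = 0.0338, adjusted p = 0.0535 with an estimated correlation). Mitosis had 7 of 23 members higher (8 adjusted over the list alone, camera adjusted p = 0.00021). Naive and central memory genes had 1 of 25 members higher and 13 lower (1 higher and 16 lower adjusted over the list alone, camera adjusted p = 3.07e-06). The receptor genes Il4ra and Il6ra stood at -1.94 ± 0.21 and -1.16 ± 0.20, and the IL-6 and STAT3 list had 4 of 17 members higher and 9 lower (4 higher and 9 lower adjusted over the list alone, camera adjusted p = 0.0319, adjusted p = 0.0535 with an estimated correlation). Without the low-count filter the latter gave an adjusted p = 0.113. Markers of other cells were lower in the mature cells. The B-cell gene Fcer2a stood at -3.71 ± 0.37, and B-cell markers had 8 of 11 members lower (9 adjusted over the list alone, camera adjusted p = 7.55e-06, adjusted p = 0.0535 with an estimated correlation). The lysozyme gene Lyz2 stood at -3.06 ± 0.24, and myeloid markers had 11 of 16 members lower (11 adjusted over the list alone, camera adjusted p = 3.07e-06, adjusted p = 0.0535 with an estimated correlation). Of 18 lung-expressed genes tested 16 were lower (camera adjusted p = 6.1e-14, adjusted p = 0.078 with an estimated correlation). In all 1471 genes passed, 701 higher and 770 lower. Without naive replicate 2 or 3 the count was 771 or 918. With the level of lung transcripts as a term, a choice made after seeing the data, it was 664. That level also parts the naive from the mature libraries, so the drop does not show how many calls lung RNA made.

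**Figure D4:**
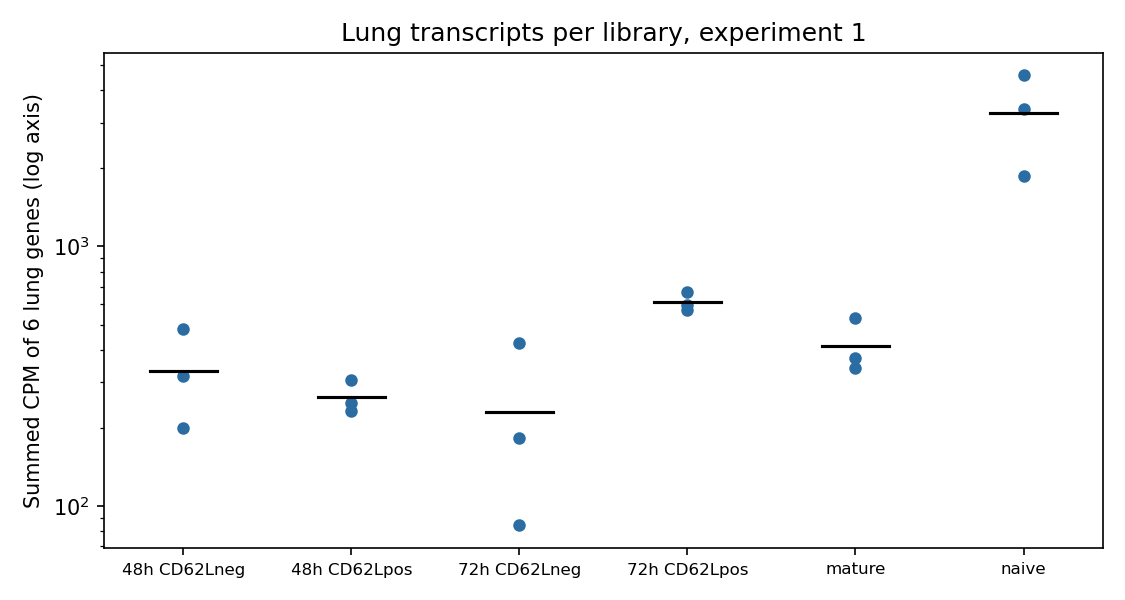
Summed CPM (log axis) of 6 lung genes in each library of experiment 1, 1 dot per library and a line at each group mean. The naive libraries lie between 1870 and 4560, above every other group.

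Comparisons that share no library were set side by side across the genes tested in both (7838 between the experiments, 8960 within experiment 1 and 9238 within experiment 2), where genes are not independent replicates. The CD62L difference of experiment 1 and that of experiment 2, each averaged over its times, had a Pearson r of 0.548 and a Spearman rho of 0.491 across genes. Of 642 genes past the test in both, 315 were higher and 321 lower in both, where independent lists would share 68.8 and 61.5. Genes that differ between CD62L positive and negative cells of experiment 1 were then counted in the concentration comparison at each time. At 18 h neither list passed, with 10 higher and 16 lower at the high concentration of the genes higher in CD62L positive cells (camera adjusted p = 0.504) and 11 higher and 17 lower of those lower there (adjusted p = 0.262). At 30 h the first list had 92 higher and 30 lower (adjusted p = 0.00131), and the second did not pass, with 53 higher and 59 lower (adjusted p = 0.548). At 48 h, of 943 tested genes that are higher in CD62L positive cells, 402 were higher and 7 lower at the high concentration (camera adjusted p = 2.56e-21). Of 802 genes lower in CD62L positive cells, 48 were higher and 412 lower at the high concentration (camera adjusted p = 1.03e-24). At 72 h the first list had 259 higher and 73 lower (adjusted p = 1.53e-05) and the second 51 higher and 260 lower (adjusted p = 1.88e-07). Both lists also moved with time alone, so their shift is not particular to concentration. From naive to 18 h the first had 41 higher and 814 lower (camera adjusted p = 4.77e-40), the second 660 and 26 (adjusted p = 2.84e-36). From 18 to 72 h the first had 726 higher and 35 lower (adjusted p = 1.08e-30), the second 84 and 537 (adjusted p = 4.64e-21). Pearson r between the CD62L difference of experiment 1 and the concentration difference was -0.041, 0.106, 0.455 and 0.219 at 18, 30, 48 and 72 h. Klf2, Lad1 and Cdkn1a, named above for the sorted cells, stood at 1.65 ± 0.22, -2.49 ± 0.23 and -0.98 ± 0.18 in the concentration comparison at 48 h. Of the 102 genes past the test at both 18 and 72 h in the concentration comparison, 80 had opposite directions. Mature against naive and CD62L positive against negative, both in experiment 1, had a Pearson r of -0.217 across genes. Of 440 genes past both of those tests 329 had opposite directions. Lung and B-cell markers, lower in mature cells and higher on the CD62L positive side, have opposite directions too, and their share in this was not tested. As lists in the mean CD62L comparison, genes lower in mature cells had a camera adjusted p = 3.38e-11 and genes higher in them an adjusted p = 0.0134, but with an estimated correlation neither passed (adjusted p = 0.103 and 0.62).

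**Figure D5:**
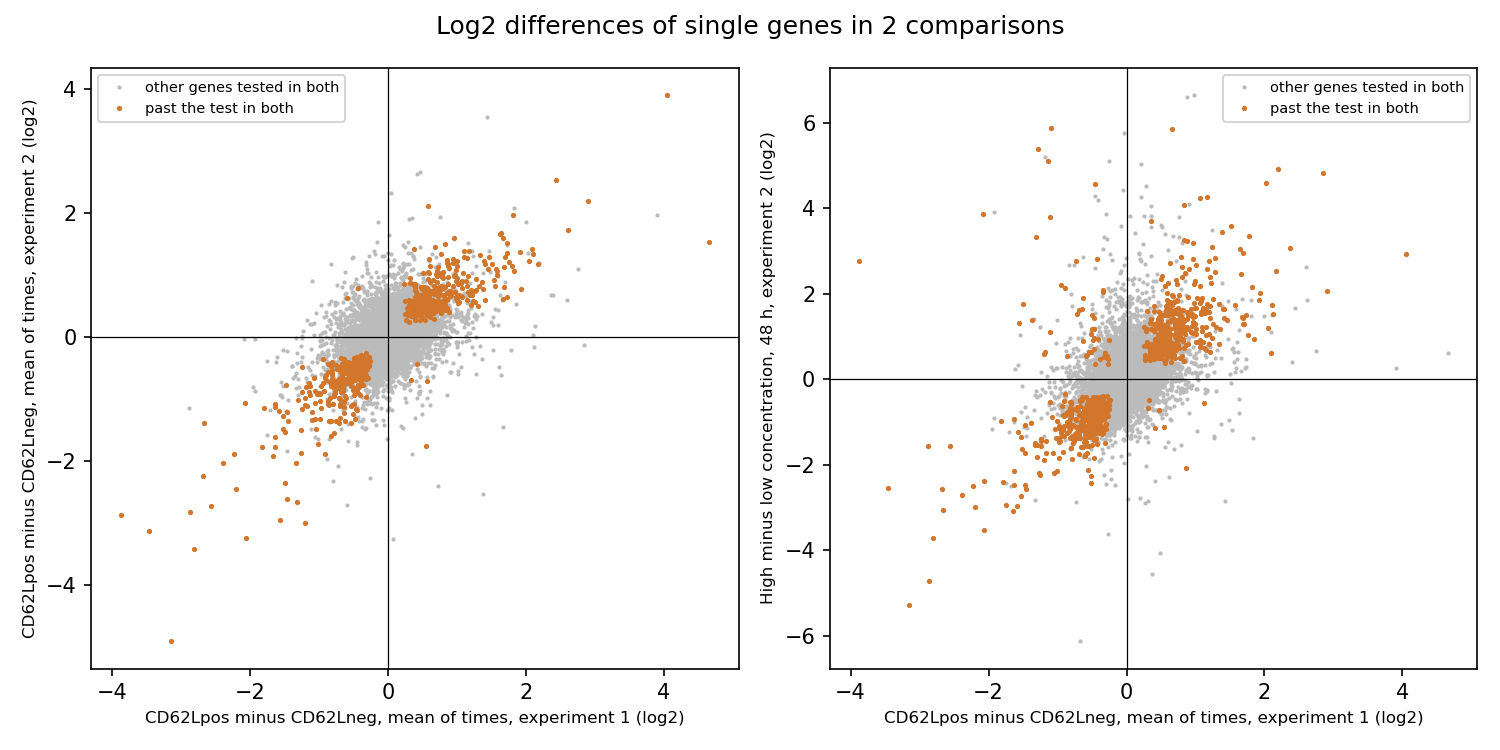
Scatter plots across genes of the log2 difference between CD62L positive and negative cells of experiment 1 (x axis, mean of 48 and 72 h) against that of experiment 2 (left) and against the log2 difference between concentrations at 48 h (right), 1 point per gene. The points past both tests lie mostly in the same-direction quadrants, 636 of 642 on the left and 814 of 869 on the right. Against the concentration difference at the times not drawn the directions agree for 27 of 54 genes at 18 h, 151 of 234 at 30 h and 519 of 643 at 72 h.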

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

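The tests of the lung transcripts, of Gapdh and of the second title number were chosen only after those results were seen, while the tests of change with time and the exchanges of labels were set beforehand.

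Between 48 and 72 h the CD62L difference changed for 169 genes of experiment 1, a difference between times by its own test. Tgm2 changed by -2.42 ± 0.27, Cish by -1.39 ± 0.18, Xbp1 by -2.14 ± 0.27, Asns by -2.43 ± 0.35 and Actn1 by 1.63 ± 0.21 (n = 3 per group). In experiment 2 it changed for 120 genes, among them Il2 at 5.70 ± 0.60, Lta at -1.64 ± 0.20, Nr4a1 at 2.80 ± 0.36, Bhlhe40 at 2.39 ± 0.33 and Drc1 at -1.68 ± 0.23.

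The concentration difference changed over the 4 times for 2821 genes. The smallest adjusted p were 9.79e-18 for Rpph1, 1.92e-16 for Slc2a3, 3.19e-15 for Egln3, 7.12e-15 for 2410006H16Rik and 6.46e-14 for Anxa2. Counts of Rpph1 are uncertain, as how well poly-T priming captures it was not tested. Lists were tested for a change of that difference from 18 to 72 h, a contrast chosen after seeing the data. The medians of the hypoxia and glycolysis lists went from -0.081 to 2.75 (camera adjusted p = 1.64e-14) and from 0.009 to 1.55 (adjusted p = 1.63e-13). Replication went from 0.89 to -1.14 (adjusted p = 8.33e-21) and mitosis from 1.10 to -0.56 (adjusted p = 4.32e-10). Type I interferon went from 0.23 to 2.05 (adjusted p = 4.01e-07), early activation from -0.29 to 0.86 (adjusted p = 4.59e-06) and cholesterol synthesis moved with an adjusted p = 9.76e-06. Ribosome biogenesis (adjusted p = 0.000583) and oxidative phosphorylation (adjusted p = 0.00171) moved down, and the naive and central memory list (adjusted p = 0.00288) and IL-6 and STAT3 (adjusted p = 0.0138) up.

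Naive libraries of experiment 1 held 6 lung genes (Sftpc, Sftpb, Scgb1a1, Cbr2, Inmt and Cyp2f2) at 3270 ± 1350 summed CPM (SD, n = 3), against 413 ± 101 in mature cells. In the CD62L positive cells at 72 h the sum was 610 ± 49.1, against 231 ± 176 in the negative cells. Expression by the T cells themselves is argued against by a sum of 0 counts in the naive libraries of experiment 2, against 1742 in those of experiment 1. A single outside source of lung RNA would keep the ratio between the 6 genes nearly constant. The ratio varied over the 18 libraries by 1.96 times what counting alone gives (chi-square per degree of freedom). Of 1000 random sets of genes 1 was as low (median 7.62), so the ratio was steadier than in most sets but not constant. Those sets were drawn from other genes of like total counts, and 4703 of 8961 tested genes differ between 48 and 72 h alone. Genes that T cells do not express could look steadier than such sets whatever their source, so this comparison cannot decide on a single source. The 6 are listed lung genes with at least 300 counts, and Ager was barred by name after the data were seen. The set was thus in part chosen on these data, and a single source is not settled. Whether each library took up an equal number of lung molecules whatever its depth stays open, since the slope of their counts on library totals was 0.8 ± 0.31 within groups and -0.02 ± 0.18 over all libraries.

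Gapdh counts of experiment 2 fell into separate ranges in 6 groups, where the libraries of a group differed 47.7- to 120-fold in CPM. Library depth is argued against, since totals in those groups differed at most 2.42-fold. A glycolytic state of the cells would move the other glycolysis genes too, but their median slope on Gapdh within groups was -0.0048 (16 genes, quartiles -0.013 to 0.0055). Read assignment that changed for many genes with pseudogenes is argued against by the ribosomal protein genes, with a median slope of 0.0062 (90 genes, quartiles -0.0011 to 0.013). A difference in counting that touches Gapdh alone may remain, as 0 of 9238 other genes had a slope over 0.5 and the highest was 0.23.

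At 72 h the concentration comparison splits the libraries as the second title number does. A technical difference between the numbers that the groups share is argued against as the whole cause: over the 2447 genes past the test at 72 h, number 2 minus number 1 within each of the 4 groups that hold both followed low minus high with slopes of -0.045 to 0.074 (± 0.0059, SE across genes), where such a cause needs slopes near 1. Libraries with different numbers did differ more than those with the same number in each of these groups (in the low concentration at 48 h by a chi-square per degree of freedom of 7.57 and 9.28 against 2.34), and their differences were partly alike between the 2 such groups at 48 h (Pearson r of 0.45 across genes) and less so between the 2 at 72 h (0.15) or across times (-0.23 to 0.047). Cell concentration, for the hypoxia and glycolysis lists, is consistent with their medians of 0.525 (adjusted p = 9.01e-05) and 0.675 (adjusted p = 7.67e-11) at 30 h, where every library has number 2. A technical difference particular to the 72 h cultures cannot be told apart from concentration there, since each of the 2 groups holds 1 number.

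Labels were exchanged among the compared libraries to see how many genes such splits call. The compared libraries were refitted alone over the genes of the main test, so that counts differ from fits of the compared groups alone that filter genes anew. In comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. There the real and the highest other count were 1691 and 0 for mature against naive, and 712 and 0 (48 h) and 1415 and 0 (72 h) for CD62L in experiment 1. They were 1039 and 0 (48 h) and 231 and 1 (72 h) for CD62L in experiment 2, and 518 and 2, 809 and 1, and 1528 and 0 for the concentrations at 18, 30 and 48 h. The real split alone reached its count (1 of 40 splits) for the mean CD62L difference of experiment 1 (1932, highest other 72) and experiment 2 (1372 and 339). The same holds for the mean concentration difference (1959 and 86) and its change with time (3031 and 775). It also holds for 72 h against 48 h in experiment 1 (4733 and 1655) and experiment 2 (3578 and 591). So it does for 72 h against 18 h (5928 and 4427) and, with 1 of 84 splits, 18 h against naive (5927 and 3811). A share of 1 of 40 is the smallest that 40 splits can give, and other splits can keep part of a real difference. Since separate mice or cultures per library are not given, these splits cannot exclude a difference between cultures. For the change of the CD62L difference with time 5 of 40 splits, the real one included, reached 168 genes in experiment 1 (highest 584). In experiment 2 such splits were 3 of 40, reaching 113 (highest 416), so chance was not excluded in either experiment. Exchanging all labels at 1 time would turn the mean CD62L difference into a change with time. It would then call the 1932 or 1372 genes of that mean. The highest counts, 584 and 416, were lower, so no such full exchange was among the splits. Whether partial exchanges carried part of the mean difference into those counts was not tested. The 72 h concentration comparison, with 3 against 2 libraries, was not split.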

How the results depend on the processing

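The lung transcript term, the comparison without 72 h and those with a single low library at 48 h are tests chosen only after the results were seen. Of the 19 counts of genes, those that moved by over 1.5 times are given here, and where no cause is named the cause was not tested. The lung term took mature against naive from 1471 to 664 genes, CD62L at 72 h in experiment 1 from 1747 to 834 and its change with time from 169 to 35. That change was 279 genes without the low-count filter and 255 by DESeq2. The lung term is tied to the groups compared. The listed lung genes summed to 2320 to 5530 CPM in naive and 438 to 708 in mature libraries. At 72 h they summed to 767 to 841 in CD62L positive and 138 to 527 in negative libraries. Such a term can lower counts whether or not lung RNA caused the calls, so the drops do not show how many calls lung RNA made. For CD62L at 72 h in experiment 2 DESeq2 gave 229 and the compared groups alone 231, against 141. The compared groups alone gave 455 genes for the concentrations at 18 h (173) and 1488 at 48 h (2397). With the second title number as a term, which is then estimated from few libraries, 1531 genes passed at 72 h (2447) and 844 for CD62L at 48 h in experiment 2 (1341). At 48 h a single low library gave 917 genes where it carries the second title number of the high libraries and 1340 and 1452 where it does not, so that the count fell with fewer libraries and moved with which was kept. Without 72 h 1562 genes changed with time. With an estimated correlation 23 tests of called genes as lists had an unadjusted p under 0.05, against 39. Leaving out each library in turn gave 771 to 1447 genes for mature against naive, 385 to 569 (48 h) and 79 to 256 (change with time) for CD62L in experiment 1, and 818 to 1480 (48 h) and 50 to 119 (72 h) in experiment 2. For the concentrations it gave 94 to 154 at 18 h, 470 to 594 at 30 h and 1421 to 2226 at 72 h. The other counts stayed within 1.5 times under the settings run.

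The naming rule gives 663 values past the test, of which 659 kept direction and call with RLE normalisation, 652 without the filter, 647 with DESeq2, 632 in the compared groups alone and 571 with each library left out in turn. Of the 219 in experiment 1 150 did with the lung term. Most of those that lost their call are left out of the text, so that its named genes are in part chosen for holding under these settings. Of 110 list tests in the text 101 kept their call with an estimated correlation and 106 without the filter. Calls that held could still have a far larger p with an estimated correlation, which the text prints mainly where a call was lost. Replicate numbers showed no pairing on average over all groups. Deviations from the group mean had a mean correlation of 0.0029 over 45 pairs of libraries with the same number in experiment 1 (-0.29 to 0.4). In experiment 2 it was 0.002 over 222 pairs (-0.45 to 0.49). Positive and negative cells of the same time were not looked at apart, so whether their numbers pair stays open. With the replicate block 1834 genes passed in the mean concentration comparison (1895 without), no count moved by over 1.5 times, and 656 of the 663 values and every call of a list in the text held. RLE and DESeq2 shifted the median log2 difference by at most 0.074, and in experiment 1 they turned the direction with more genes in 3 comparisons. The share of higher genes went from 51.8% to 45.4% (RLE) and 45.6% (DESeq2) for 72 h against 48 h, from 52% to 47.4 and 48% for CD62L at 72 h, and from 52.9% to 48.7 and 49.3% for the mean CD62L difference. Depth limits the naive cells of experiment 1, whose smallest library has 58750 counts. Of simulated 2-fold changes 41.8% were found for mature against naive and for the concentrations at 18 h, and 34.3% for the concentrations at 72 h. For changes with time in experiment 2 it was 7.46% (CD62L) and 11.9% (concentration).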

Other observations

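The tests of ribosomal protein genes were chosen only after the results were seen. Ccr6, a chemokine receptor gene of Th17 and other memory cells, was lower at the high concentration, at -1.84 ± 0.20 on average over the 4 times, and stood at -1.77 ± 0.22, -2.83 ± 0.23 and -2.52 ± 0.45 at 30, 48 and 72 h, but was not past the test at 18 h, at -0.25 ± 0.50 (n = 3 per group and time, 2 for low at 72 h). In CD62L positive cells of experiment 2 it was also lower, at -3.52 ± 0.29 at 48 h. The Th17 list had 0 of 3 members past the test (1 lower adjusted over the list alone, camera adjusted p = 0.497) at 18 h, 2 of 3 members lower (3 adjusted over the list alone, camera adjusted p = 0.00112) at 30 h, 2 of 3 members lower (2 adjusted over the list alone, camera adjusted p = 0.0022) at 48 h and 1 of 3 members lower (1 adjusted over the list alone, camera adjusted p = 0.233) at 72 h. Without the low-count filter its adjusted p at 18 h was 0.025. For CD62L at 48 h in experiment 2 it had 2 of 3 members lower (2 adjusted over the list alone, camera adjusted p = 0.00127). Ccr8, a chemokine receptor gene found on Th2 cells, was lower at the high concentration on average, at -0.96 ± 0.27. Ecm1, of the same Th2 list, was higher, at 2.50 ± 0.23 at 48 h. At 48 h the Th2 list had 1 of 5 members higher and 3 lower (1 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.132). In experiment 1 the Th2 cytokine gene Il13 was lower in CD62L positive cells at 72 h, at -2.96 ± 0.43, and over both times the Th2 list had 2 of 3 members lower (2 adjusted over the list alone, camera adjusted p = 0.00502).

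Other cell types were also measured by their markers. Cd8b1, a CD8 coreceptor gene, was lower in mature than in naive cells, at -2.44 ± 0.32, and higher at the high concentration by 0.78 ± 0.12. The CD8 and NK list had 1 of 6 members higher and 2 lower (1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.405) for mature against naive, and without the low-count filter its adjusted p = 0.0302. The hemoglobin gene Hbb-b2, whose counts are shared with its duplicate Hbb-bt, was at -2.88 ± 0.45 in mature against naive cells. It was at -1.02 and not past the test with the level of lung transcripts as a term, a choice made after seeing the data. That level parts the naive from the mature libraries, so the lost call does not show its cause. The red cell and platelet list had 4 of 5 members lower (4 adjusted over the list alone, camera adjusted p = 0.000228, adjusted p = 0.0535 with an estimated correlation), beside the lung and B-cell markers, with both names of each duplicated hemoglobin gene counted. Of 90 ribosomal protein genes, which have many pseudogenes and are uncertain, 37 were higher and 2 lower at the high concentration at 72 h (camera adjusted p = 2.86e-08, adjusted p = 0.396 with an estimated correlation). Between 18 and 72 h 6 rose and 49 fell (camera adjusted p = 0.00032, adjusted p = 0.509 with an estimated correlation).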
